A study of Mus musculus with 8 samples.

How the data were processed

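The samples were macrophages sorted from enzymatically digested whole aortas of male Ldlr-/- mice (lacking the low-density lipoprotein receptor) that had eaten a Western diet for 16 weeks. The sort took viable cells positive for CD45, CD11b and CD64. Control mice (Ctrl) carried a Lipa transgene at Rosa26 that Cre recombinase switches on, but no Cre. M-LipaKI littermates carried in addition 1 copy of LysMCre, a Cre inserted in the lysozyme gene Lyz2. Each genotype had 4 libraries, and each library pooled 2 to 3 mice, 10 mice per genotype, per the labels' protocols. RNA input was 10 ng per sample. Complementary DNA was made and amplified with the SMART-Seq v4 Ultra Low Input kit and made into libraries with Nextera XT, per the labels' protocols. That chemistry does not mark the strand, so reads from exons that overlap another gene are not told apart by strand. Among the genes named in the text such exons occur in Map4k5, Itgav, Ndufa2, Tk1, Ftl1, H2-DMa, Ddit3, Acaa1a, Tgm2, Egfl7, Lipe, Ltc4s, mt-Co1 and mt-Co3. They also occur in Mt2, Cxcl10, Irf1 and mt-Atp6.

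Quantification by the authors ended in a table of estimated counts per gene and a table of values on a log2 scale. The submitters' processing notes name Salmon 1.10.2, MultiQC and DESeq2 1.40.0, and the genome builds GRCm39 and mm10, without saying which build was used for what. The step that summed transcripts to genes, the annotation release and any trimming are not given in the sources used here. The deposited estimated counts covered 54307 Ensembl genes, were not scaled and were not filtered, and 22.0% of the values were not whole numbers. Salmon divides reads that match several transcripts between them by its model, so genes with near-identical copies, or genes that overlap, are uncertain. The deposited log2 values covered 16737 rows, and their name in the deposit marks them as regularized-log (rlog) values. Their deviations from each gene's mean followed those of log2 counts-per-million values (CPM) at a correlation of 0.977 across 5889 highly counted genes, which are not independent replicates. Differences between batches remained in them. The rlog table repeated 114 gene identifiers, of which the first row was kept. All 8 columns of each table were matched to a library by name.

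The estimated counts were rounded to whole numbers. Library totals ran from 42732402 to 53525610 counts, and 18111 to 21629 genes had at least 1 count. In the shallowest library a count of 0 allowed up to 0.0702 CPM (3 counts of the total), and such limits cover counting error only, because amplified reads without molecular identifiers are not independent molecules. Gene symbols came from the reference annotation (GENCODE M21) for 51482 genes and from the rlog table for a further 40. Only 0.0644% of the versioned gene identifiers equalled those of that annotation, so it served for names, transcript lengths, GC content and neighbour relations, and no coordinates are given. The counts of no pair of libraries agreed within sampling noise. The closest pair, M-LipaKI 2 and 4, had a chi-square of 25.4 per degree of freedom over genes.

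Genes were kept with edgeR's filterByExpr by genotype at its defaults (14915 genes). Library sizes were scaled by TMM. Genotypes were compared with edgeR's quasi-likelihood test (robust dispersion and robust quasi-likelihood fit, two-sided, genotype as the only term), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Standard errors of log2 fold changes were taken from the fitted change and its F statistic, and intervals are 95%. CPM values use TMM-scaled library sizes, and log2 CPM has a prior count of 2. Lipa and Lyz2 also had an exact two-sided permutation test of log2 CPM over the 70 label arrangements, whose smallest possible p is 0.0286. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and the figures were drawn with matplotlib 3.10.9.

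Gene lists were fixed before the data were examined, 37 in all, for processes, cell types and technical checks. They were tested with camera at a preset correlation of 0.01 over the 36 lists with at least 5 measured members, two-sided, with Benjamini-Hochberg adjustment. The same test with an estimated correlation, fry and an exact permutation test of each list's mean log2 CPM stand beside it. For each list, member genes were also adjusted over the list alone. Shares of all counts taken by the marker lists of other cell types were compared with exact two-sided permutation tests, adjusted over the 12 cell lists. The genes named in the text were chosen by a rule written beforehand. It took Lipa, Lyz2 and Ldlr, then in each direction up to 10 genes past the threshold, filled up to 5 with the smallest p among known genes with a mean of at least 50 counts and the same sign in all 4 batch pairs, then the 3 members of smallest p of each process list and up to 2 of each other list. Tnf, Abca9, Ltc4s, Gadd45b, Itgb3, Dock1, Itga6, Gclc, Mt1, Mt2 and Ms4a7 were named after their values were seen. So were Fcer1g, Rtp4, Cxcl10, Irf1, Parp14, Cpt1a, Ace, Col3a1, Wdfy4, mt-Co2 and mt-Atp6.

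The labels give each library a batch number from 1 to 4 that is also its replicate number, and each batch holds 1 library of each genotype. The numbers therefore pair the libraries. Deviations of the paired libraries from their genotype's mean correlated at 0.546, 0.314, 0.398 and 0.162 in batches 1 to 4 (across genes), and 7 of the 8 libraries correlated best with the library of the same number. The labels state no model with batch, so the batch block was an alternative. Other alternatives planned beforehand were DESeq2 size factors, upper-quartile factors, no filter beyond 1 count in total, a mean of at least 50 counts, the DESeq2 Wald test, limma-voom with sample quality weights, limma on the rlog values, the batch block in DESeq2, other thresholds, and each library left out in turn. Corrections for transcript length and GC content (a smooth trend per library) and limma-voom with the batch block were added after the data were seen. So were both batch 1 libraries left out, Lyz1 left out of its list and Lyz2 left out of the core macrophage list. Transcript length and GC content of a gene were medians over all its annotated transcripts, which need not be those present in these cells. The length correction of the DESeq2 model with the batch block also changed the genes and the scaling. It covered the 14863 filtered genes with a length and used TMM scaling, against 28401 genes and DESeq2 size factors without it. A call lost under it is therefore not due to length for certain.

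The tests were tried on simulated counts for the same genes, libraries and dispersions, with 50 genes changed at each of 4 folds. In the comparison of M-LipaKI with Ctrl simulated without a batch term, edgeR recovered 0% of genes changed 1.5-fold, 18.0% at 2-fold, 50.0% at 3-fold and 68.0% at 4-fold, with 5 unchanged genes among 73 calls over 14456 genes. DESeq2 recovered 8.0%, 54.0%, 70.0% and 80.0% at those folds, with 50 unchanged genes among 156 calls over 14915 genes. With the batch block, edgeR recovered 2.0%, 34.0%, 82.0% and 80.0% (8 unchanged among 107 calls, 14430 genes), and DESeq2 28.0%, 70.0%, 94.0% and 84.0% (58 unchanged among 196 calls, 14915 genes). A list of 24 genes shifted 1.5-fold was called by camera in both models and no other list was called. Simulated genes were drawn independently of each other, whereas the estimated correlation within the real ribosomal protein list was 0.907. The simulation therefore does not show how often camera calls unchanged lists of correlated genes.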

Results

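RNA was sequenced from macrophages sorted out of the aortas of Ldlr-/- mice on a Western diet, in 4 control libraries (Ctrl) and 4 libraries from littermates whose myeloid cells carried an active Lipa transgene (M-LipaKI). The comparison asks how raised Lipa, the lysosomal acid lipase that releases cholesterol and fatty acids from lipoprotein lipids, alters these cells. Ctrl mice carried the transgene without Cre, so the genotypes differ in the transgene's activation and in the Cre insertion together. Library totals ran from 42732402 to 53525610 counts, with 18111 to 21629 genes detected. The most abundant transcripts were those of Apoe at 3.72% of all counts, Spp1 at 2.35%, Ctsb at 2.33%, Lyz2 at 2.21% and Ftl1 at 2.09%. In a principal component analysis of the libraries the first 3 components held 44.1%, 22.6% and 14.5% of the variance.

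Lipa transcripts (ENSMUSG00000024781.17) were more abundant in M-LipaKI macrophages. They averaged 545 ± 142 counts-per-million (CPM; SD, n = 4) in Ctrl and 881 ± 76.0 CPM in M-LipaKI, a ratio of 1.62 (95% interval 1.18 to 2.21). Every M-LipaKI library lay above every Ctrl library, with ranges of 825 to 991 and 334 to 641 CPM, and Lipa was higher in 4 of 4 batch pairs. The log2 change was 0.69 with a standard error of 0.20. The exact two-sided permutation test gave p = 0.0286, the smallest that 70 arrangements allow, and the exact sign-flip test of the 4 pairs gave 0.125, its smallest. Across all genes the edgeR adjusted p was 0.355, and with the batch as a block in DESeq2 it was 0.0237. Counts do not separate the transgene's transcripts from those of the endogenous gene. Ldlr (ENSMUSG00000032193.10), the receptor gene knocked out in both genotypes, had 56.5 ± 9.78 CPM in Ctrl and 50.4 ± 2.47 CPM in M-LipaKI (n = 4 each). Their ratio was 0.892 (0.707 to 1.13, exact permutation p = 0.371), so no difference was detected with this model. Over the alternatives the ratio of Ldlr ran from 0.731 to 0.986.

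**Figure D1:**
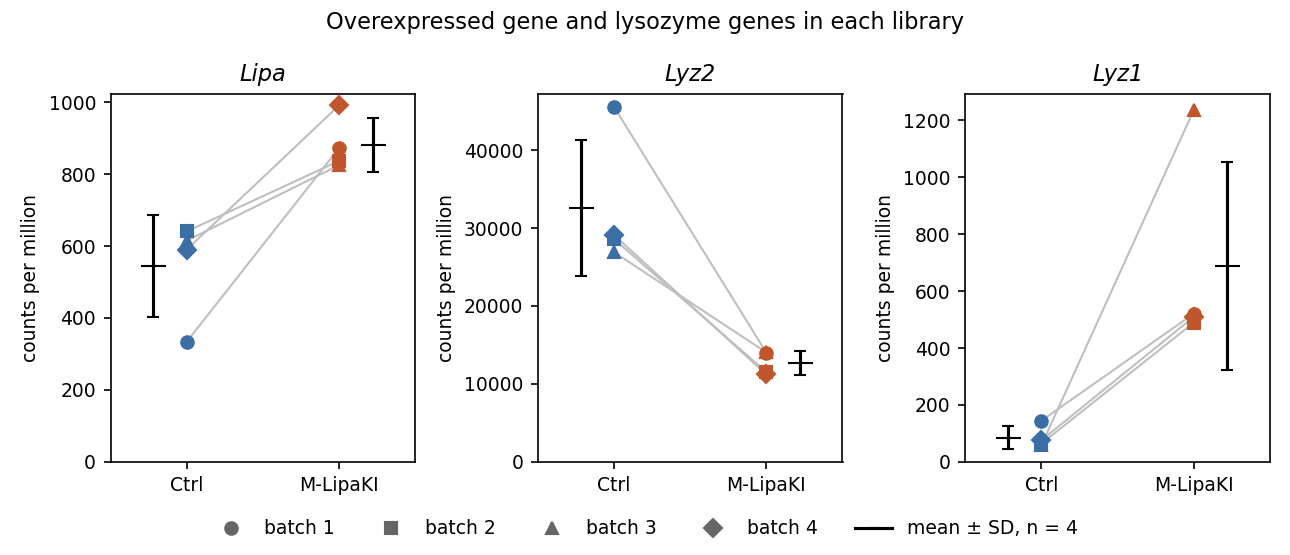
Counts-per-million values (vertical axes, linear) of Lipa, Lyz2 and Lyz1 in each library by genotype, with marker shapes for the 4 batches, grey lines joining libraries of a batch, and black bars for the mean ± SD (n = 4). Lipa was between 825 and 991 CPM in M-LipaKI and between 334 and 641 CPM in Ctrl, while M-LipaKI libraries were lower for Lyz2 and higher for Lyz1.

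Both lysozyme genes differed between the genotypes. Lyz2 (ENSMUSG00000069516.9), the macrophage lysozyme gene that carries the Cre, averaged 32532 ± 8723 CPM in Ctrl and 12689 ± 1540 CPM in M-LipaKI, a ratio of 0.390 (0.291 to 0.523), and was lower in 4 of 4 pairs. Its neighbour Lyz1 (ENSMUSG00000069515.7), a lysozyme gene of intestinal Paneth cells, averaged 85.2 ± 40.0 CPM in Ctrl and 688 ± 365 CPM in M-LipaKI, a ratio of 8.08 (4.17 to 15.7), and was higher in 4 of 4 pairs. For each gene the exact two-sided permutation p was 0.0286 (n = 4 each), and the edgeR adjusted p was 0.355. Both passed in DESeq2 with genotype alone, with adjusted p = 5.1e-06 for Lyz2 and 4.2e-10 for Lyz1. The transcripts of these genes share 422 sequences of 31 bases, 34.2% of those of Lyz1, so assignment of reads between them is uncertain. Of the 16 measured genes on the list of neighbours of the Cre insertion, 12 had higher fitted values, with a median log2 change of 0.16, and camera did not call the list (adjusted p = 0.0854). The direction-free form of fry called it (adjusted p = 0.00378), and the directional form did not (0.227). In edgeR none of its members passed over all genes, and 1, Lyz1, was higher when adjusted over the list alone. Lyz1 also passed over all genes in limma-voom and, with the block as without it, in DESeq2. Rap1b, a small GTPase gene, was at 899 ± 149 CPM in Ctrl and 689 ± 37.4 in M-LipaKI. Without Ctrl 3 the neighbour list was called (camera adjusted p = 0.0452), and without Lyz1 as a member its adjusted p was 0.428.

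Across all genes, edgeR found none of 14915 past an adjusted p of 0.05 (smallest 0.355). At an unadjusted p under 0.05 there were 2065 genes, 663 higher and 1402 lower in M-LipaKI. Without any change 745.75 would be expected on average, and correlated genes spread that number widely, as the splits of the libraries given later show. The count of 2065 was 3018 without Ctrl 2 and 2180 without Ctrl 4. It was 1869 without Ctrl 1, 1185 without Ctrl 3, 1287 without M-LipaKI 1, 733 without M-LipaKI 2, 1798 without M-LipaKI 3 and 1045 without M-LipaKI 4. With the batch as a block in edgeR 1343 were higher and 1390 lower, and without Ctrl 1 there were 970 higher and 899 lower. DESeq2 was run on the 28401 genes with at least 1 count. Its own filters left 14389 of these without an adjusted p, and 17620 with the batch as a block. DESeq2 called 15 genes, 6 higher and 9 lower, among them a gene at a log2 change of -24.2 (standard error 3.38). In limma-voom with sample weights 2 were called (Lyz1 and Lyz2), and limma on the deposited rlog values called 0. With the batch as a block edgeR called 0 genes, limma-voom 6, and DESeq2 773, of which 398 were higher and 375 lower. The DESeq2 fits with and without the block shared 14 genes. Among the genes of smallest p that did not pass in edgeR, those higher in M-LipaKI were Lyz1, Togaram1, a gene of ciliary microtubules (10.8 to 20.1 CPM), Ranbp2, of the nuclear pore (18.2 to 31.6), Osbp, an oxysterol-binding protein that moves cholesterol between membranes (25.1 to 51.1), and Map4k5, a kinase gene (11.6 to 19.3). Those lower were Lyz2, the monocyte-attracting chemokine Ccl12 (175 to 101 CPM), Hilpda, an inhibitor of lipid droplet lipolysis (51.1 to 29.8), the histone gene Hist1h2ap (40.2 to 19.0) and Taf7, of the general transcription machinery (15.7 to 8.14). Of the 36 gene lists tested with camera at a preset correlation, 11 were called, 3 higher and 8 lower in M-LipaKI, and with an estimated correlation none was. The exact permutation test of each list's mean log2 CPM called 0 lists. Among the 11, its unadjusted p ran from 0.0286 for autophagy to 0.343 for immediate early genes. With 70 arrangements a single list cannot pass that test after adjustment, so its outcome does not show that lists were alike.

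Most inflammatory genes had lower values in M-LipaKI macrophages. Of 42 measured members of the cytokine and NF-kB list 33 had lower fitted values, and the median log2 change was -0.38 (camera adjusted p = 1.7e-05, and adjusted p = 0.708 with an estimated correlation). No member passed over all genes in edgeR, and 4 were lower when adjusted over the list alone. These were the chemokine genes Ccl7 (375 ± 130 CPM in Ctrl, 176 ± 14.6 in M-LipaKI), Ccl2 (349 ± 109 and 170 ± 23.7) and Ccl4 (191 ± 53.9 and 98.3 ± 13.6), which draw in monocytes and lymphocytes, and Tnf (132 ± 28.4 and 75.1 ± 16.0), chosen after its values were seen. All 4 were lower in 4 of 4 pairs (n = 4 per genotype). With the batch as a block in edgeR 7 were lower when adjusted over the list alone. With the batch block in DESeq2, 9 members were lower and none higher over all genes. Without Ctrl 4 the list was not called (camera adjusted p = 0.111, median -0.12; over all alternatives adjusted p ran from 6.3e-10 to 0.708), while Ccl2, Ccl7, Ccl4 and Tnf stood at ratios of 0.543, 0.544, 0.570 and 0.577. The dissociation and immediate early list, of genes that tissue digestion can induce, moved the same way. Of its 37 members 29 had lower fitted values (median -0.30, camera adjusted p = 0.00572, and adjusted p = 0.788 with an estimated correlation). None passed over all genes or adjusted over the list alone. With the block, in DESeq2 over all genes and in edgeR over the list alone, Nfkbia, an NF-kB inhibitor (752 to 482 CPM), Ier3 (188 to 115) and Gadd45b (158 to 108, chosen after its values were seen) were lower. That list was not called without Ctrl 3 (median -0.19, adjusted p = 0.218) or Ctrl 4 (-0.21, 0.166) in camera. Interferon response genes were not called (45 members, median -0.16, camera adjusted p = 0.151), and in edgeR 0 passed over all genes and 0 adjusted over the list alone. They were called lower without Ctrl 1 (adjusted p = 0.00101), Ctrl 4 (0.00973) or M-LipaKI 3 (0.00701) in camera, and examples were Xaf1 (27.3 to 16.9 CPM), the antiviral membrane protein gene Ifitm3 (485 to 287) and Ifi205 (15.2 to 7.04), whose ratio was 0.464 and 0.735 without Ctrl 1. With the block in DESeq2 5 were lower and 1 higher, namely Xaf1, Ifitm3, Rtp4 (55.1 to 31.8 CPM), Irf1 (106 to 75.0) and Cxcl10 (22.3 to 12.7), and Parp14 (23.1 to 32.6), the last 4 chosen after their values were seen. Of these Cxcl10 (log2 change -0.73 before and -0.62 after, DESeq2 adjusted p = 0.0719) and Parp14 (0.53 and 0.26, 0.214) did not pass after a length correction.

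**Figure D2:**
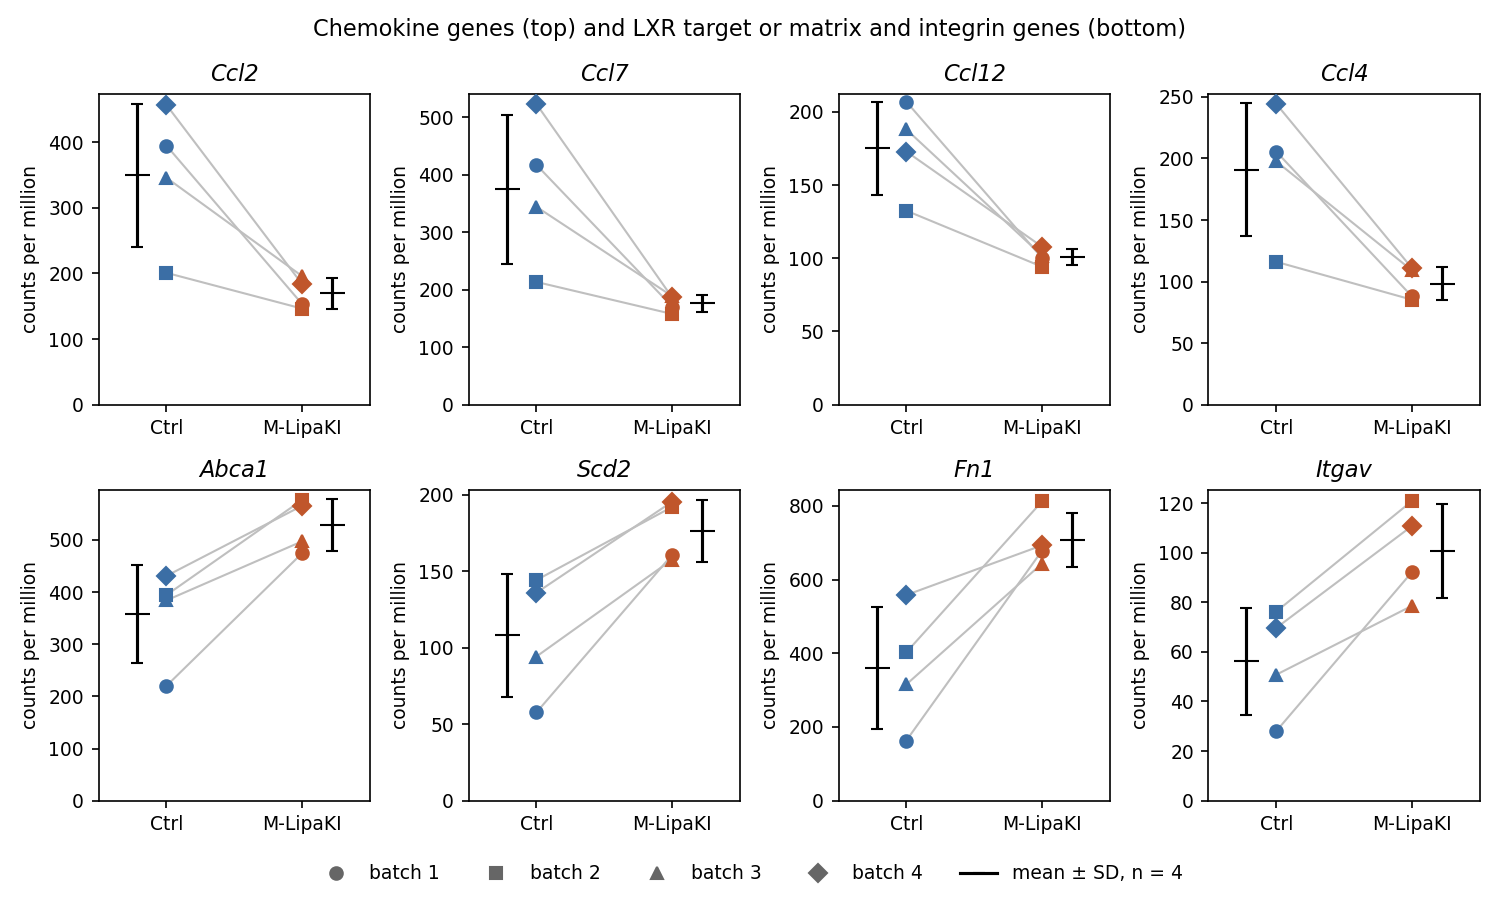
Counts-per-million values (vertical axes, linear) of 4 chemokine genes (top) and of Abca1, Scd2, Fn1 and Itgav (bottom) in each library, with marker shapes for the 4 batches, grey lines joining libraries of a batch, and black bars for the mean ± SD (n = 4). In each of the 4 batches the chemokine genes were lower and the other genes higher in M-LipaKI, with means of 349 and 170 CPM for Ccl2 and 357 and 529 CPM for Abca1.

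Several genes on a list of cholesterol-sensing receptor targets and cholesterol efflux genes, Abca1 among them, had higher values in M-LipaKI macrophages. The list covers the liver X receptors (LXR), nuclear receptors that respond to oxysterols, with their targets and cholesterol efflux genes, so not every member is an LXR target. It had 25 measured members, of which 16 had higher fitted values (median log2 change 0.14, camera adjusted p = 0.0433, and adjusted p = 0.733 with an estimated correlation). Abca1, the exporter of cholesterol to apolipoprotein A-I, averaged 357 ± 93.7 CPM in Ctrl and 529 ± 50.3 in M-LipaKI, and Scd2, a fatty acid desaturase, 108 ± 40.1 and 177 ± 20.1 (n = 4 each). Ldlrad3, at 11.8 ± 4.91 CPM in Ctrl, had a ratio of 1.70. No member passed over all genes in edgeR or adjusted over the list alone. With the batch block in DESeq2, 4 members were higher and none lower, namely Abca1, Scd2, Ldlrad3 and Abca9 (86.2 to 152 CPM, chosen after its values were seen). After a length correction of that model Abca1 (log2 change 0.61 before and 0.31 after, DESeq2 adjusted p = 0.111), Scd2 (0.79 and 0.53, 0.0528) and Ldlrad3 (0.84 and 0.59, 0.135) did not pass. The list was not called without Ctrl 4 (median 0.15, camera adjusted p = 0.102), M-LipaKI 3 (0.16, 0.107) or M-LipaKI 4 (0.10, 0.0737), nor with the length and GC correction (0.13, 0.0657) or a mean of at least 50 counts (0.12, 0.0696). It was called without Ctrl 1 (median 0.067) and without Ctrl 2 (0.23). Cholesterol synthesis genes were not called (24 members, median 0.01, camera adjusted p = 0.786). Among them were Hmgcr, the rate-limiting enzyme (19.8 to 29.5 CPM), Lss (7.05 to 9.79) and Ebp (75.8 to 62.5), and 0 members passed over all genes or adjusted over the list alone.

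Most autophagy genes had higher values in M-LipaKI macrophages, and the lysosomal lists were not called. Of 35 autophagy genes 26 had higher fitted values (median log2 change 0.21, camera adjusted p = 0.0344, and adjusted p = 0.708 with an estimated correlation). Pik3c3, a lipid kinase that starts autophagosomes, was at 28.5 ± 4.00 CPM in Ctrl and 36.8 ± 2.18 in M-LipaKI, the cargo receptor gene Nbr1 at 72.8 ± 26.6 and 115 ± 13.4, and Rragd at 11.3 ± 4.07 and 17.8 ± 3.97 (n = 4 each). Nbr1 alone was higher with the block in DESeq2. The autophagy list was not called without Ctrl 4 (median 0.18, camera adjusted p = 0.0704) or M-LipaKI 3 (0.22, 0.0785), nor with a mean of at least 50 counts (0.19, 0.0588), the length and GC correction (0.18, 0.0636) or both batch 1 libraries left out (0.15, 0.0639). Lysosomal hydrolases (40 members) had a median of 0.10 (camera adjusted p = 0.151, and 0.0195 without Ctrl 2), with Manba (82.3 to 134 CPM) and Galc (53.6 to 87.6), which cleave sugars from glycoproteins and galactolipids, higher with the block in DESeq2, and Fuca1 at 347 and 296 CPM. Galc did not pass after a length correction of that model (log2 change 0.79 before and 0.53 after, DESeq2 adjusted p = 0.0856). Lysosomal membrane and proton pump genes (29 members) had a median of -0.10 (camera adjusted p = 0.217), with the pump subunit genes Atp6v0e (526 to 360 CPM), Atp6v1f (241 to 162) and Atp6v1g1 (396 to 270). Atp6v1f was lower with the block in DESeq2 (log2 change -0.53, adjusted p = 0.0479), and not after its length correction (-0.44, 0.0684). Foamy and lipid-associated macrophage genes (25 members) had a median of -0.11 (camera adjusted p = 0.929), with Emp1 (202 to 312 CPM), Lgals3 (6482 to 5043) and Itgax (269 to 422). Emp1 was higher with the block in DESeq2 (log2 change 0.65), and not after its length correction (0.47, DESeq2 adjusted p = 0.128). Triglyceride and lipid droplet genes (23 members) had a median of 0.05 and a mean of -0.10 (camera adjusted p = 0.786). In that list Hilpda was lower when adjusted over the list alone, beside Hsd17b11 (15.5 to 8.55 CPM), which was with the batch as a block, and Lpin2 (26.0 to 39.8). Hilpda and Hsd17b11 were lower and Lpin2 higher with the block in DESeq2. Fatty acid oxidation and PPAR genes (33 members) had a median of -0.11 (camera adjusted p = 0.324), with Etfb (125 to 83.4 CPM), Eci1 (34.5 to 24.8) and Acaa1a (145 to 121). With the block in DESeq2 Cpt1a (115 to 175 CPM, chosen after its values were seen) was higher and Etfb lower (log2 change -0.58), the latter not after its length correction (-0.36, DESeq2 adjusted p = 0.0852). In the autophagy, hydrolase, pump, foamy and oxidation lists 0 members passed in edgeR over all genes and 0 when adjusted over the list alone, with or without the block.

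Most integrin and matrix genes had higher values in M-LipaKI macrophages. Of 45 measured members 34 had higher fitted values (median log2 change 0.29, camera adjusted p = 0.00186, and adjusted p = 0.708 with an estimated correlation). Fn1, fibronectin, averaged 360 ± 165 CPM in Ctrl and 707 ± 73.2 in M-LipaKI, the protease gene Adam9 218 ± 66.8 and 331 ± 23.6, and Itgav, the alpha-v integrin, 56.2 ± 21.6 and 101 ± 18.9 (n = 4 each). Each was higher in 4 of 4 pairs, and with the batch block in DESeq2 6 members were higher and none lower. Adam9 was among the 6 and did not pass after a length correction of that model (log2 change 0.66 before and 0.40 after, DESeq2 adjusted p = 0.104). Without M-LipaKI 1 the median of the list was 0.16, and it was called (camera adjusted p = 0.0330). Efferocytosis and scavenger receptor genes, for the uptake of dead cells, were not called (35 members, median 0.10, camera adjusted p = 0.255). With the block in DESeq2 3 of them were higher, Itgav, its partner Itgb3 (4.40 to 10.6 CPM) and Dock1 (21.0 to 35.1), of which Itgb3 and Dock1 were chosen after their values were seen. Dock1 did not pass after the length correction (log2 change 0.85 before and 0.64 after, DESeq2 adjusted p = 0.0708). The complement genes C1qb (7414 to 5701 CPM) and C1qc (4615 to 3642) were lower in 4 of 4 pairs. Alternative activation genes (27 members) had a median of -0.11 and a mean of -0.06 while camera gave the direction as higher (adjusted p = 0.835), with Fn1, Il10 (15.3 to 9.58 CPM) and Tgm2 (368 to 550), of which Fn1 was higher with the block in DESeq2. In edgeR 0 members of these lists passed over all genes, and 0 when adjusted over the list alone. With the batch as a block 5 integrin and matrix genes were higher when adjusted over the list alone, namely Fn1, Adam9, Itgav, Itgb3 and Itga6 (139 to 229 CPM, chosen after its values were seen), and 1 of the efferocytosis list, Itgb3.

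Several antioxidant and cell cycle genes had lower values in M-LipaKI macrophages, in lists whose calls ended under several alternatives, and resident-type macrophage genes were not called. Resident-type genes (29 members) had a median log2 change of -0.27 and were not called (camera adjusted p = 0.208), but were with the batch as a block (median -0.24, 0.0413, and adjusted p = 0.827 with an estimated correlation), without Ctrl 2 (0.0468) and without M-LipaKI 3 (0.0369). Ccl8 (819 to 491 CPM), Cbr2 (525 to 326), Pf4 (388 to 221) and Ltc4s (46.3 to 24.8, chosen after its values were seen) were lower with the block in DESeq2. After a length correction of that model Ccl8 (log2 change -0.68 before and -0.42 after, DESeq2 adjusted p = 0.0843), Cbr2 (-0.64 and -0.45, 0.0731) and Pf4 (-0.75 and -0.38, 0.136) did not pass. Of 26 NRF2 and oxidative stress genes 17 had lower fitted values (median -0.31, camera adjusted p = 0.0342, and adjusted p = 0.708 with an estimated correlation), among them the peroxidase gene Gpx1 (3367 to 2360 CPM), the ferritin light chain Ftl1 (24296 to 17882) and Blvrb (201 to 145). With the block in DESeq2 Gpx1, Blvrb, Mt1 (285 to 175 CPM) and Mt2 (32.6 ± 23.4 to 19.1 ± 9.84, n = 4 each) were lower, the last 2 chosen after their values were seen, and the ratio of Mt2 was 0.926 without Ctrl 1. After a length correction of that model Gpx1 (log2 change -0.50 before and -0.41 after, DESeq2 adjusted p = 0.0568), Blvrb (-0.46 and -0.36, 0.0588) and Mt2 (-0.67 and -0.35, 0.274) did not pass. The NRF2 list was not called without Ctrl 4 (median -0.25, camera adjusted p = 0.111) or M-LipaKI 2 (-0.24, 0.0862), nor after the length correction (-0.27, 0.127), the length and GC correction (-0.29, 0.110) or the batch block with length correction (-0.27, 0.108), or on rlog values (-0.22, 0.0934). Without Ctrl 1 it was called with a median of -0.18. Of 36 cell cycle genes 22 had lower fitted values (median -0.07, camera adjusted p = 0.0369, and adjusted p = 0.788 with an estimated correlation), and the list was not called with the batch as a block (-0.07, 0.0948). Tk1, thymidine kinase (24.5 to 15.1 CPM), Stmn1 (173 to 103) and Hmgb2 (94.5 to 54.5) were lower with the block in DESeq2, and Tk1 did not pass after its length correction (log2 change -0.67 before and -0.58 after, DESeq2 adjusted p = 0.0624). The cell cycle list was not called without Ctrl 3 (median -0.049, camera adjusted p = 0.218), Ctrl 4 (-0.023, 0.137), M-LipaKI 1 (-0.0087, 0.268) or M-LipaKI 3 (-0.031, 0.0950), nor after the length correction (-0.092, 0.0638), the length and GC correction (-0.072, 0.0711) or the batch block with length correction (-0.094, 0.135). It was called without Ctrl 1 (median -0.13), Ctrl 2 (-0.029) or M-LipaKI 2 (-0.14). MHC class II genes (14 members) had a median of -0.28 (camera adjusted p = 0.222, and 0.00960 without M-LipaKI 3), with H2-DMa (274 to 197 CPM), H2-Ab1 (5121 to 4113) and Ctss (8406 to 6853), and H2-DMa was lower with the block in DESeq2. ER stress genes (28 members) had a median of 0.06 (camera adjusted p = 0.324), with Canx (349 to 499 CPM), Ddit3 (35.3 to 21.4) and Sesn2 (11.2 to 19.2). Canx and Sesn2 were higher and Ddit3 lower with the block in DESeq2, Sesn2 not after a length correction (log2 change 0.89 before and 0.64 after, DESeq2 adjusted p = 0.0868). Glycolysis and hypoxia genes (29 members) had a median of 0.04 and a mean of -0.01 (camera adjusted p = 0.934), with Mif (86.8 to 60.1 CPM), Pfkfb3 (49.5 to 84.4) and Bnip3 (56.0 to 40.7). Pfkfb3 was higher and Mif lower with the block in DESeq2, Mif not after a length correction (log2 change -0.52 before and -0.32 after, DESeq2 adjusted p = 0.0955). In these lists 0 members passed in edgeR over all genes, and 0 when adjusted over the list alone without the block. With it 10 NRF2 genes were lower and 1 higher when adjusted over the list alone, the higher one being Gclc (30.5 to 41.8 CPM, chosen after its values were seen). So adjusted, Ccl8, Cbr2, Pf4 and Ltc4s were lower in the resident-type list.

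**Figure D3:**
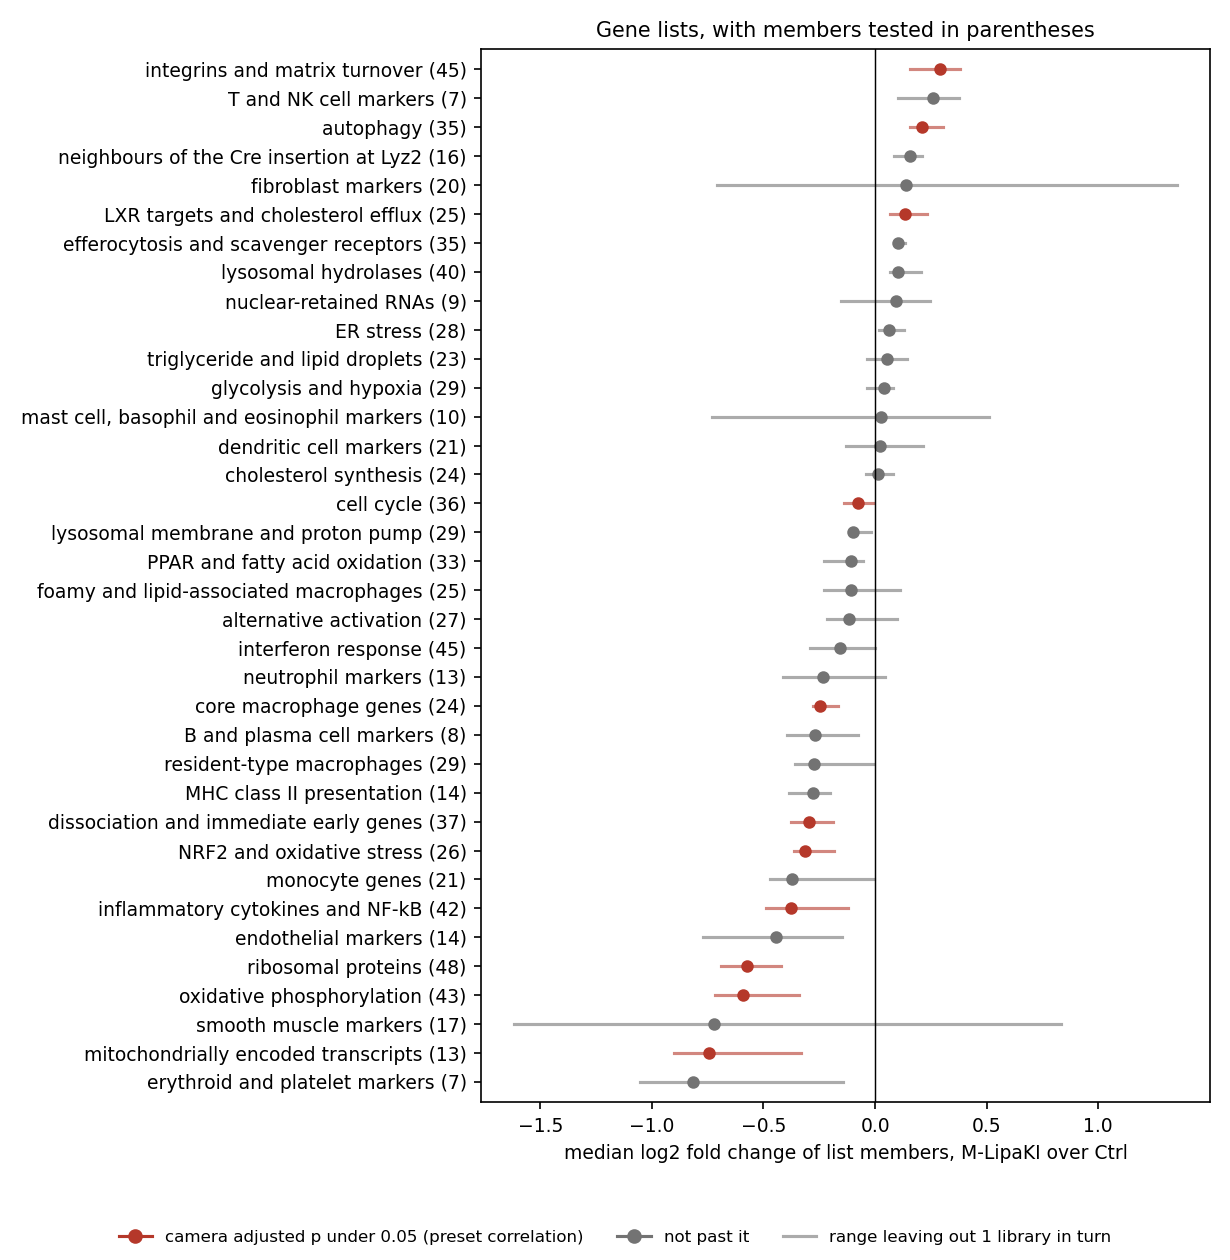
Median log2 fold change of the members of each gene list, M-LipaKI over Ctrl (horizontal axis), with red points for lists past a camera adjusted p of 0.05, grey points for the others, and lines for the range when each library is left out. Medians ran from 0.29 for integrins and matrix turnover to -0.82 for erythroid and platelet markers, which were not called.

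Most transcripts of ribosomal proteins and of the respiratory chain had lower values in M-LipaKI macrophages, in lists that were not called with an estimated correlation. All 48 measured ribosomal protein genes had lower fitted values (median log2 change -0.57, camera adjusted p = 2.9e-22, and adjusted p = 0.708 with an estimated correlation), for example Rps15 (92.5 ± 30.3 to 52.8 ± 5.70 CPM) and Rps14 (238 ± 66.9 to 147 ± 17.7; n = 4 each). Of 43 nuclear genes of oxidative phosphorylation 40 had lower fitted values (median -0.59, camera adjusted p = 1.9e-14, and adjusted p = 0.708 with an estimated correlation), for example Cox6a1 (279 to 173 CPM), Ndufa2 (136 to 81.9) and Sdhb (278 to 203). All 13 mitochondrially encoded transcripts had lower fitted values (median -0.74, camera adjusted p = 3.4e-06, and adjusted p = 0.708 with an estimated correlation), for example mt-Co3 (1828 ± 1396 to 842 ± 123 CPM) and mt-Co1 (1581 ± 782 to 941 ± 104; n = 4 each), and the log2 change of mt-Co3, -1.12, was -0.41 without Ctrl 1. The list was not called after the length and GC correction (median -0.20, camera adjusted p = 0.135). Its members held 1.15% of counts in Ctrl 1 and 0.390 to 0.636% in the other Ctrl libraries, and its median was -0.33 without Ctrl 1 and -0.38 without batch 1 (camera adjusted p = 6.5e-05 and 4.3e-05). Without Ctrl 1 the oxidative phosphorylation median was -0.34 (camera adjusted p = 5.0e-13). In edgeR 0 members of these lists passed over all genes, and adjusted over the list alone 34 ribosomal, 23 oxidative phosphorylation and 0 mitochondrially encoded genes were lower. So adjusted with the batch as a block, 43, 30 and 13 were lower. With the batch block in DESeq2 over all genes, 29, 15 and 2 were lower. The last 2, chosen after their values were seen, were mt-Co2 (704 ± 393 to 384 ± 58.1 CPM) and mt-Atp6 (1008 ± 519 to 580 ± 81.8; n = 4 each). After a length correction of that model neither passed (log2 changes -0.72 and -0.67 before, -0.62 and -0.57 after, DESeq2 adjusted p = 0.0733 and 0.0780). These transcripts are short, and fold changes followed transcript length, with a median of -0.24 in the eighth of genes with the shortest transcripts and 0.30 in the longest (Spearman 0.301 across 14863 genes, which are not independent replicates). The deviation of Ctrl 1 was 0.36 in the shortest and -0.42 in the longest eighth. Nuclear-retained RNAs (9 members) were not called (median 0.09, camera adjusted p = 0.960), with Gas5 at 30.5 and 18.3 CPM and Pvt1 at 5.59 and 4.24 CPM in Ctrl and M-LipaKI. In edgeR 0 of them passed over all genes and 0 adjusted over the list alone. Gas5 was lower with the block in DESeq2 (log2 change -0.65, adjusted p = 0.0429), and not after its length correction (-0.50, 0.0840).

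**Figure D4:**
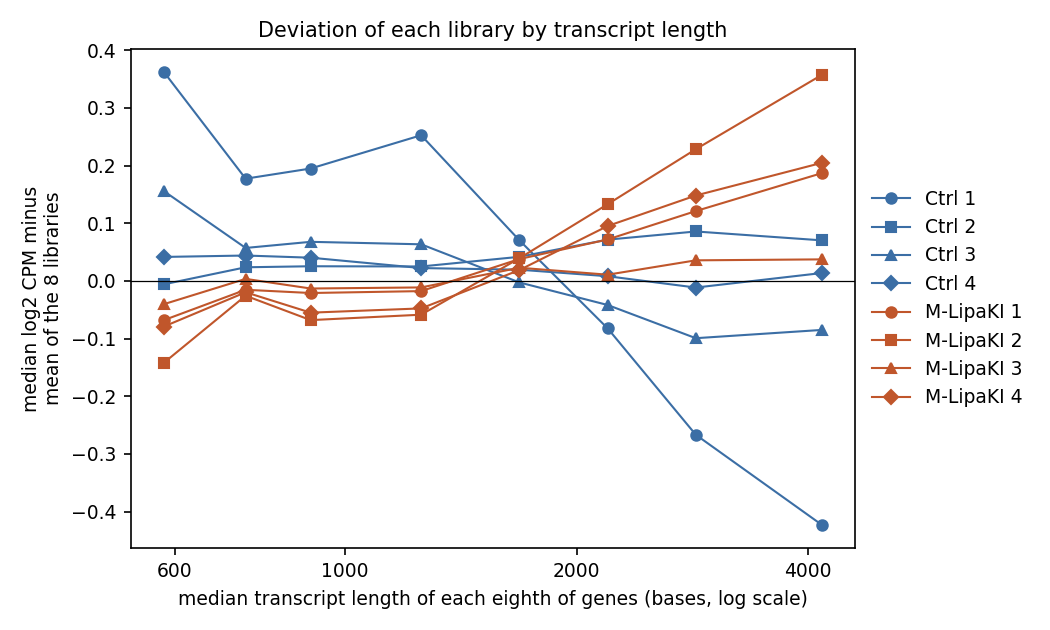
Median deviation of each library's log2 CPM from the mean of the 8 libraries (vertical axis) for eighths of genes ordered by transcript length, against the median length of each eighth (horizontal log axis, bases). Ctrl 1 ran from 0.36 in the shortest eighth to -0.42 in the longest, and M-LipaKI 2 from -0.14 to 0.36.

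Markers of other cell types took small shares of the counts in both genotypes. Core macrophage genes held 6.97 ± 0.645% of counts in Ctrl and 4.86 ± 0.232% in M-LipaKI (exact permutation p = 0.0286, adjusted p = 0.343 over 12 lists, n = 4 each), a list that includes Lyz2. Lyz2 alone held 3.11% in Ctrl and 1.31% in M-LipaKI, which is 1.80 of the 2.12 percentage points between the genotypes. Without Lyz2 the list held 3.86 ± 0.188% and 3.55 ± 0.143% (exact permutation p = 0.0571, n = 4 each). With 70 arrangements and 12 lists a single share cannot pass this test after adjustment, so its outcome does not show that shares were alike. Smooth muscle markers held 0.196% of counts in Ctrl 1 and 0.00822 to 0.0305% in the other Ctrl libraries, and fibroblast markers 0.672% in Ctrl 1 and 0.601% in M-LipaKI 1. By camera the core macrophage list was lower (24 members, 16 with lower fitted values, median log2 change -0.25, adjusted p = 0.0222, and adjusted p = 0.708 with an estimated correlation), with Lyz2 lower when adjusted over the list alone and Aif1 at 228 and 125 CPM in Ctrl and M-LipaKI. It was not called without Ctrl 3 (median -0.17, camera adjusted p = 0.0560), Ctrl 4 (-0.22, 0.0971) or M-LipaKI 1 (-0.26, 0.0502), nor on rlog values (-0.12, 0.105) or with Lyz2 left out of the list (-0.21, 0.127). Monocyte genes (21 members) had a median of -0.37 (camera adjusted p = 0.383), with S100a4 at 128 and 79.5 CPM. With the block in DESeq2 Fn1 and Ace (7.67 to 15.8 CPM, chosen after its values were seen) were higher and S100a4 lower (log2 change -0.64), the last not after a length correction (-0.28, DESeq2 adjusted p = 0.242). Smooth muscle markers (17 members) had a median of -0.72 (camera adjusted p = 0.423) with Tpm2 at 44.4 ± 70.8 and 13.5 ± 9.62 CPM (n = 4 each) and Des at 1.46 and 0.406. Without Ctrl 1 their ratios were 1.51 and 0.533, and without M-LipaKI 1 they were 0.198 and 0.116, against 0.304 and 0.280 with all libraries. They were called lower without Ctrl 3 (0.0452) or M-LipaKI 1 (0.0340), and their median was 0.83 without Ctrl 1 (camera adjusted p = 0.123). Fibroblast markers (20 members) had a median of 0.14 (camera adjusted p = 0.654, and 0.00433 without Ctrl 1) with Col1a1 at 30.3 ± 14.1 and 98.7 ± 105 CPM and Col1a2 at 77.1 ± 53.1 and 206 ± 227 (n = 4 each), each higher in 3 of 4 pairs. Their ratios of 3.25 and 2.67 were 1.68 and 1.30 without M-LipaKI 1. Col1a2 and Col3a1 were higher with the block in DESeq2. Col3a1 (219 ± 170 to 457 ± 462 CPM, n = 4 each, chosen after its values were seen) had a ratio of 2.09, or 1.15 without M-LipaKI 1. Col1a2 did not pass after a length correction of the DESeq2 model (log2 change 0.89 before and 0.83 after, DESeq2 adjusted p = 0.0654). In edgeR 0 members of these 4 lists passed over all genes, and adjusted over the list alone only Lyz2 did. With the batch as a block Aif1, C1qb, Ms4a7 (1450 to 956 CPM) and Fcer1g (1344 to 900) were also lower in the core macrophage list when adjusted so, the last 2 chosen after their values were seen. Over all genes in DESeq2 with the block, Lyz2, Aif1, Ms4a7 and Fcer1g were lower, Ms4a7 (log2 change -0.56 before and -0.48 after, DESeq2 adjusted p = 0.0509) and Fcer1g (-0.55 and -0.44, 0.0559) not after a length correction.

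The remaining cell type lists were not called by camera, and in edgeR 0 of their members passed over all genes and 0 when adjusted over the list alone. With the batch as a block 1, Pf4 of the erythroid and platelet list, was lower when adjusted over the list alone. Over all genes in DESeq2 with the block, Pf4 and Cst3 were lower and Kdr and Wdfy4 (18.8 to 27.8 CPM, chosen after its values were seen) higher. Pf4 (log2 change -0.75 before and -0.38 after, DESeq2 adjusted p = 0.136) and Wdfy4 (0.69 and 0.40, 0.166) did not pass after a length correction. Endothelial markers (14 members) had a median log2 change of -0.44 (camera adjusted p = 0.344), with Kdr at 7.70 CPM in Ctrl and 15.0 in M-LipaKI and Egfl7 at 2.15 and 1.12. T and NK cell markers (7 members) had a median of 0.26 (camera adjusted p = 0.465), with Klrb1c at 0.188 ± 0.217 and 0.651 ± 0.204 CPM (ratio 3.47, and 7.40 without Ctrl 1) and Cd2 at 4.86 and 3.68. B and plasma cell markers (8 members) had a median of -0.27 (camera adjusted p = 0.324), with Ighm at 255 and 195 CPM and Cd79b at 8.50 and 7.24. Dendritic cell markers (21 members) had a median of 0.02 and a mean of 0.05 while camera gave the direction as lower (adjusted p = 0.786), with Cst3 at 2545 and 1705 CPM and Batf3 at 17.3 and 12.1. Neutrophil markers (13 members) had a median of -0.23 (camera adjusted p = 0.705), with Il1r2 at 16.5 ± 12.4 and 7.48 ± 2.57 CPM (ratio 0.454, and 0.702 without Ctrl 4) and S100a8 at 3.65 and 1.98. Mast cell, basophil and eosinophil markers (10 members) had a median of 0.03 (camera adjusted p = 0.786), with Siglecf at 2.38 and 4.06 CPM and Gata2 at 0.610 ± 0.693 and 1.13 ± 0.612 (ratio 1.84, and 4.19 without Ctrl 3; n = 4 each). Erythroid and platelet markers (7 members) had a median of -0.82 (camera adjusted p = 0.331), with Ppbp at 22.3 ± 36.9 and 2.48 ± 0.784 CPM, which in Ctrl 4 was at 77.5 CPM (ratio 0.111, and 0.643 without Ctrl 4), and Pf4. Adipocyte markers had 4 measured members and were not tested (median 0.06), with Acsl1 at 51.9 and 72.7 CPM and Lipe at 11.5 and 14.5.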

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

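All tests of explanations in this part were chosen after the results were seen. A library stood far from the other 3 of its genotype, by a gap to its nearest neighbour above the 95% critical value of Dixon's test, in 30 of 354 groups of values, where 17.7 would arise by chance (about 1 in 20), and 11 of the 30 came from Ctrl 1.

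In Ctrl 1, Lipa was at 334 CPM (590 to 641 in the other Ctrl libraries), Lyz2 at 45540 CPM (26899 to 29105), Atp6v0e at 730 CPM, Ifi205 at 31.5 CPM, Ftl1 at 30477 CPM, Ctss at 11446 CPM, Tpm2 at 150 CPM, Mt2 at 67.5 CPM and Dock1 at 8.59 CPM. In the same library smooth muscle markers held 0.196% of counts (0.00822 to 0.0305% in the others) and nuclear-retained RNAs 0.103%. In Ctrl 3 the mean log2 CPM was 8.19 for the resident-type list and 4.11 for the triglyceride list and Irf1 was at 148 CPM, and in Ctrl 4 Ppbp was at 77.5 CPM (1.56 to 6.36 in the others).

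In M-LipaKI 1, Osbp was at 42.8 CPM, Wdfy4 at 15.6 CPM, and B and plasma cell markers held 0.0189% of counts. In M-LipaKI 2, Atp6v1f was at 138 CPM, Ndufa2 at 64.1, Ier3 at 75.6 and Rps15 at 44.4 CPM, and the mean log2 CPM was 7.09 for the NRF2 list and 6.53 for the ER stress list. In M-LipaKI 3, Lyz1 was at 1235 CPM (489 to 521 in the other M-LipaKI libraries), Togaram1 at 19.1 CPM and H2-Ab1 at 5400 CPM. In that library the mean log2 CPM of endothelial markers was -1.35, immediate early genes held 2.29% of counts, and neighbours of the Cre insertion held 0.246%.

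The lower Lyz2 and higher Lyz1 of M-LipaKI libraries have technical and biological candidate explanations. Reads shared between the paralogs in a constant share would lower Lyz1 along with Lyz2, and the tables argue against it, since the lower 95% bound of the Lyz1 ratio was 4.17. Lyz2 reads counted as Lyz1 would need a Lyz1 gain near the Lyz2 loss, and the gain was 3.04% of the loss (1.19 to 9.16% over the batch pairs), which argues against it for the fall of Lyz2. For the rise of Lyz1, such reads at the rate seen in Ctrl are argued against, since Lyz1 stood at 3.72 to 8.80% of Lyz2 in M-LipaKI and at 0.214 to 0.316% in Ctrl, and a rate altered by the Cre-carrying allele was not tested. Loss of 1 Lyz2 copy to the Cre insertion remains open, since the interval of the Lyz2 ratio of 0.390 (0.291 to 0.523, and 0.315 to 0.501 with the batch block) held 0.5, and Ctrl lacks Cre, so the design does not separate the insertion from Lipa.

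The lower ribosomal protein, oxidative phosphorylation and mitochondrially encoded lists may reflect a difference between libraries in the yield of short transcripts. A trend with annotated length as the whole cause is argued against, since the medians were -0.57, -0.59 and -0.74 before its correction and -0.42, -0.37 and -0.54 after. Camera at its preset correlation called 3 of the 3 lists after it. A gene's length here was the median over its annotated transcripts, for example 634 bases for Manba and 708 for Canx. Where that differs from the transcripts present the correction can be too weak, so a trend with true length stays open. After a length and GC correction 2 of the 2 nuclear lists were called (medians -0.46 and -0.37), whereas the mitochondrially encoded list went from a median of -0.74 to -0.20 (adjusted p = 0.135 in camera), so a trend with length and GC content stays open for that list. Chance cannot be excluded, since 2 of the 35 splits of the 8 libraries moved the mean of the 3 lists as far (0.546 for the real split, 0.621 for the highest other), and the 8 splits that part all 4 batch pairs are too few for a share under 0.05 (0.410 for the highest other, with 1 split, the real one, as far), while each list was lower in 4 of 4 pairs. A lower expression of these genes with the genotype also stays open and was not tested apart from these.

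The lower inflammatory list may rest in part on Ctrl 4, since without it the list was not called (adjusted p = 0.111 in camera; over all alternatives 6.3e-10 to 0.708). Ccl2 and Ccl7 without Ctrl 4 had ratios of 0.543 and 0.544. A trend with annotated length is argued against, since the median was -0.38 before and -0.37 after its correction. The adjusted p of 1.1e-06 after it in camera rests on the preset correlation and does not decide this. A weaker response to tissue dissociation cannot be told apart, since the immediate early list was lower in 3 of 4 batch pairs and 4 pairs are too few. Chance cannot be excluded, since 6 of the 35 splits moved the list mean as far (0.286 for the real split, 0.351 for the highest other). The 8 that part all 4 batch pairs are too few for a share under 0.05 (0.273 for the highest other, with 1 split, the real one, as far). The list was lower in 4 of 4 pairs, but unevenly. Its mean log2 ratios were -0.19, -0.025, -0.067 and -0.86 in batches 1 to 4. An effect of the genotype stays open.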

How the results depend on the processing

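Alternatives with a length or GC correction, limma-voom with the batch block, the batch 1 libraries left out or Lyz1 or Lyz2 off a list were chosen after the results were seen, and the others, like the gene lists and tests, before the data were examined. Lipa was higher and Lyz2 lower, each at an unadjusted p under 0.05, under every alternative run (log2 changes 0.54 to 0.79 and -1.44 to -1.03), with adjusted p from 0.0237 to 0.706 for Lipa and 5.8e-12 to 0.706 for Lyz2. The count of genes past the threshold, 0 in edgeR, was 15 in DESeq2, 2 in limma-voom with weights, 773 in DESeq2 with the batch block, 536 with that block and the length correction (382 shared with the 773) and 6 in limma-voom with the block. Beside the edgeR count of 0, 2065 genes had an unadjusted p under 0.05. It stayed 0 in edgeR under every scaling, filter, threshold, correction and left-out library, and in limma on rlog values. On simulated counts over 14915 genes DESeq2 with the block called 58 unchanged genes among 196. The real fit that called 773 was run on 28401 genes, and the length-corrected one on 14863. The number of called lists, 11, was 7 with the length and GC correction (6 of the 11 and the Cre neighbours) and 0 with an estimated correlation. It was 0 by the exact permutation test of list means and 0 by fry, whose direction-free form called 1, the Cre neighbours. By camera the number was 5 to 13 with 1 library left out, where the 5 without Ctrl 4 were 4 of the 11 and the interferon list. The batch block changed the call of the cell cycle and resident-type lists and of no other list. The Cre neighbour median, 0.16 and not called by camera, was 0.084 to 0.21 with 1 library left out. Camera called that list with the length correction (0.29), with length and GC (0.28), with block and length (0.32) and without batch 1 (0.15). The 8 libraries allow too few arrangements for a single share of the 12 cell type lists to pass after adjustment, so those tests say nothing about stability.

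The following medians, none of a called list, changed sign, and the cause was not tested. With the batch block and length correction they were 0.031 for lysosomal membrane genes, 0.0092 for alternative activation, -0.0063 for dendritic, -0.091 for mast cell and 0.088 for erythroid markers, and -0.13 for nuclear-retained RNAs. With a mean of at least 50 counts they were -0.0059 for cholesterol synthesis, -0.030 for dendritic and -0.11 for mast cell markers, and -0.14 for nuclear-retained RNAs. On rlog values they were 0.0040 for B cell, -0.018 for dendritic and 0.0054 for neutrophil markers, and -0.0045 for nuclear-retained RNAs. With the length and GC correction they were -0.034 for fibroblast and -0.015 for dendritic markers, with the length correction -0.15 for nuclear-retained RNAs, and with the batch block -0.23 for mast cell markers. Without batch 1 they were 0.069 for alternative activation, 0.10 for erythroid markers and -0.0086 for nuclear-retained RNAs. With 1 library left out the ranges were -0.040 to 0.080 for cholesterol synthesis, -0.23 to 0.11 for foamy genes, -0.22 to 0.10 for alternative activation, -0.035 to 0.14 for triglyceride genes and -0.035 to 0.080 for glycolysis. They were -1.62 to 0.83 for smooth muscle, -0.71 to 1.35 for fibroblast, -0.13 to 0.21 for dendritic, -0.41 to 0.043 for neutrophil and -0.73 to 0.51 for mast cell markers, and -0.15 to 0.25 for nuclear-retained RNAs. Tpm2, at -1.72, was 0.44 in limma-voom with weights and -2.33 to 0.59 with 1 library left out. Depth limits the marker genes near the floor, where 3 counts in the shallowest library are 0.0702 CPM.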

Other observations

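The count of unadjusted calls was compared across splits, and the random lists and the chromosomal neighbourhood were added, after the result was seen, and the other split counts in this part were planned. For genes past the edgeR threshold all 35 splits of the 8 libraries gave 0, as did the real one (highest other 0), where 2065 genes had an unadjusted p under 0.05, DESeq2 called 15 and limma-voom 2. For that unadjusted count chance cannot be excluded, since 2 of the 35 splits gave as many (2065 for the real split, 2396 for the highest other, which set M-LipaKI 3 with Ctrl 1, Ctrl 3 and Ctrl 4 and parts only 2 of the 4 batch pairs). For gene lists called, 17 of the 35 splits gave as many (11 for the real split, 17 for the highest other), so chance cannot be excluded. The 8 splits that part all 4 batch pairs are too few for a share under 0.05. Among them the unadjusted edgeR count was 2065 for the real split and 341 for the highest other (2733 and 431 with the batch block), and 1 split, the real one, gave as many. DESeq2 with the batch block called 773 genes for the real split and 10 for the highest other, and 1 split, the real one, gave as many. Camera with the block called 11 lists for the real split and 14 for the highest other, and 3 splits gave as many.

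Against 10000 random lists of the same size, matched on transcript length and expression, the median of the integrin and matrix list lay at percentile 99.97, that of the autophagy list at 96.6 and that of the LXR and cholesterol efflux list at 83.5. The NRF2 list lay at percentile 0.670, the core macrophage list at 1.19 and the cell cycle list at 7.12. The ribosomal protein, oxidative phosphorylation, mitochondrially encoded, inflammatory and immediate early lists lay at percentile 0, with random lists at medians of -0.19, -0.18, -0.11, 0.032 and 0.0057. These percentiles do not test chance over the 8 libraries, since random lists lack the co-expression of the real ones. The estimated correlation was 0.907 in the ribosomal and 0.949 in the mitochondrially encoded list. Random lists were also not matched on GC content. Among genes at an unadjusted p under 0.05, 32.1% were higher in M-LipaKI, and 51.6% without Ctrl 1. Within the chromosomal neighbourhood of Lyz2, 25 genes were tested, of which 5 had an unadjusted p under 0.05 and 1, Lyz1, passed when adjusted within the neighbourhood.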
